A study of Mus musculus with 30 samples.

How the data were processed

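Gene expression was measured in mouse B cells on 30 Affymetrix whole-genome mouse expression arrays, 1 per culture, in 10 groups of 3. The cells were resting mature B cells enriched from spleen, of the C57BL/6 B1-8i strain per the labels. They came either from Irf4+/+ mice (wild type) or from Irf4-/- mice carrying an Irf4 gene that doxycycline switches on (called KO here at every dose). Wild-type cells were taken at days 0, 1 and 3. KO cells were taken at day 0, and at days 1 and 3 with 0, 16 or 100 ng/mL doxycycline (zero, low and high DOX). Day 0 cells were not stimulated, and the others were cultured with CD40 ligand, IL-2, IL-4 and IL-5. Each replicate came from a separate mouse, per the series text, which adds that 2 replicates of each group were handled together and 1 on another occasion, without saying which. The labels do not say whether the KO cultures of different doses and days came from the same mice.

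RNA was extracted with Trizol, its quality was checked on a Bioanalyzer, and total RNA went into biotin-labelled cRNA, per the labels' protocols and the series text. The deposited values are linear signal intensities, 1 per probe set and array, which the authors normalized with D-Chip using a model of the perfect-match probes only, per the series text. The submitters' processing notes also name MAS5, with no role, so its part is not given in the sources used here. The deposited intensities spanned 1 to 30619.06 with a median of 188.2, and 62 of them equalled 1. Median intensities of the 30 arrays lay between 171 and 199. The log2 difference between the 3' and 5' Actb control probe sets lay between 0.11 and 0.27. For Gapdh this difference was 0.25 on the array of KO day 0 replicate 2 and between -0.083 and 0.044 on the other 29 arrays, so that array stood apart. In the same group replicate 3 correlated least with the others (0.9831 and 0.9786, against 0.9906 between replicates 1 and 2) and had the lowest of the array weights (0.254, against 0.423 for replicate 2). Both were kept. Signals of arrays give no counting depth, and the number of arrays limits the precision. Every column of the table matched a sample by its title.

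Of 45101 probe sets, 64 were control sets and were left out. GEO's platform annotation gave 34945 of the others 1 gene symbol, 932 several and 9160 none, and sets with several symbols or none were not named. Of the sets with 1 symbol, 34741 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6 and 204 kept the annotation's name. That table served only for names and for the order of neighbouring genes, and no coordinates are given. A probe set was tested if at least 3 of the 30 arrays exceeded the table's median, which left 26095 sets, 21668 of them with 1 symbol. Each gene was represented by its tested probe set of highest mean, giving 12183 genes, of which 5472 had several tested sets. Where another set of a named gene moved the other way past the threshold, this is stated.

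Intensities were raised by 16 and put on the log2 scale with no further normalization. A linear model with 1 mean per group was fitted to all 30 arrays in limma 3.58.1 (lmFit, contrasts.fit and eBayes) under R 4.3.3, which leaves 20 residual degrees of freedom. The median residual SD was 0.097. P-values were adjusted by Benjamini-Hochberg over the 12183 genes within each comparison, and genes with adjusted p under 0.05 are called changed. Differences are log2 values of the group named first minus the other, SE is the standard error from limma, and SD is the spread of 3 arrays. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so single genes rest on limma's test, which shares its spread over all groups. The comparisons were KO against wild type at each day, each dose against the others at days 1 and 3, each later day against day 0 within genotype, the interaction of genotype with day 3 against day 0, and the high and low DOX cultures against wild type at day 3. At day 3, genes were also sorted into those rising or falling at both dose steps and those in which low DOX differed from both zero and high DOX in the same direction.

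The rule for named genes, the gene lists, the tests and most alternatives were set before the data were examined. In each comparison the named genes were those with the largest changes in each direction among called genes whose 3 arrays in one group all lay above all 3 in the other, which 10% of unchanged genes do by chance. The interaction compares 4 groups, so its named genes were taken by size among called genes without that condition. The 10 largest each way were taken in 4 main comparisons (KO zero DOX and wild type at day 3, high and zero DOX at day 3, high and low DOX at day 3, wild type at days 3 and 0) and the 5 largest each way elsewhere. Unnamed transcripts and immunoglobulin variable genes were passed over. To these were added a fixed panel of B cell and plasma cell regulators, and from each gene list up to 4 members with the largest changes. The 24 gene lists held B cell and plasma cell programmes, metabolic and stress genes, and markers of T, myeloid, NK, dendritic and erythroid cells. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the lists within each comparison. Where a list's call is lost with the estimated correlation, that adjusted p is printed beside it. Counts "adjusted over the list alone" use Benjamini-Hochberg within the list.

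The fit and the list tests were tested on simulated data for all 30 arrays. Group means were kept, except that high DOX at day 3 was given the zero DOX means before genes were changed. Noise was drawn independently for each gene and array, so correlation between genes and between KO arrays of a number was left out. The shares that follow hold only for that setting. Among 12183 genes, 96% of 100 genes changed 2-fold and 76% of 100 changed by 0.5 log2 were recovered, with 3.91% false calls. Replicates of 1 group correlated at 0.9786 to 0.9982 across genes, and at most 0.047% of values were identical between any of the 435 pairs of the 30 arrays, so no array repeated the values of another. Same-numbered KO arrays deviated together from their group means: over genes, their deviations correlated at 0.30 to 0.86 in 21 of 21 pairs of KO groups. Between KO and wild type these correlations ran from -0.31 to 0.25, and among wild-type groups from -0.053 to 0.24. The numbers thus pair the KO arrays. Among wild-type arrays different numbers correlated at a mean of -0.062, so any pairing there was weak but is not excluded. A fit with the replicate number as a block was run as an alternative. Expression of Xist and Y-linked genes showed that KO replicates 1 and 2 came from males, and KO replicate 3 and every wild-type array from females. The labels do not give the sex of the mice.

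The alternatives were quantile normalization, centring each array on its median, no filter and a stricter one, offsets of 1 and 64, only the compared arrays in the fit, the replicate block, trend and robust moderation, array weights, each probe set on its own, and each array left out in turn. After the data were seen, a block within genotype, a fit without a pair of day 1 arrays of doubtful label, both together, and a term for sex were added, as were splits that keep the pairing of the KO arrays and simulated overlaps of calls. The seed of the simulation with shared controls was changed after its first run because it equalled a printed count, which moved the simulated values. Figures were drawn with matplotlib 3.10.9, and tables were handled with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and the R package data.table (version 1.17.8). Genes of the lists without a probe set of their own symbol were not analysed here.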

Results

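Genome-wide transcript levels were measured in mouse splenic B cells that differ in Irf4, the transcription factor whose dose steers activated B cells toward plasma cells. Cultures stimulated through CD40 with IL-2, IL-4 and IL-5 were sampled from wild-type mice and from Irf4-/- mice in which doxycycline restores Irf4. There were 3 arrays, each from an individual mouse, in each of 10 groups: wild type at days 0, 1 and 3, KO at day 0, and KO at days 1 and 3 with zero, low or high DOX. Of 12183 genes tested, between 0 and 9932 changed in the comparisons made. The comparisons ask what loss of Irf4 changes before and during activation, and what graded restoration of Irf4 returns. Median array intensities lay within 171 to 199, and the 3 arrays per group limit the precision.

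**Figure D1:**
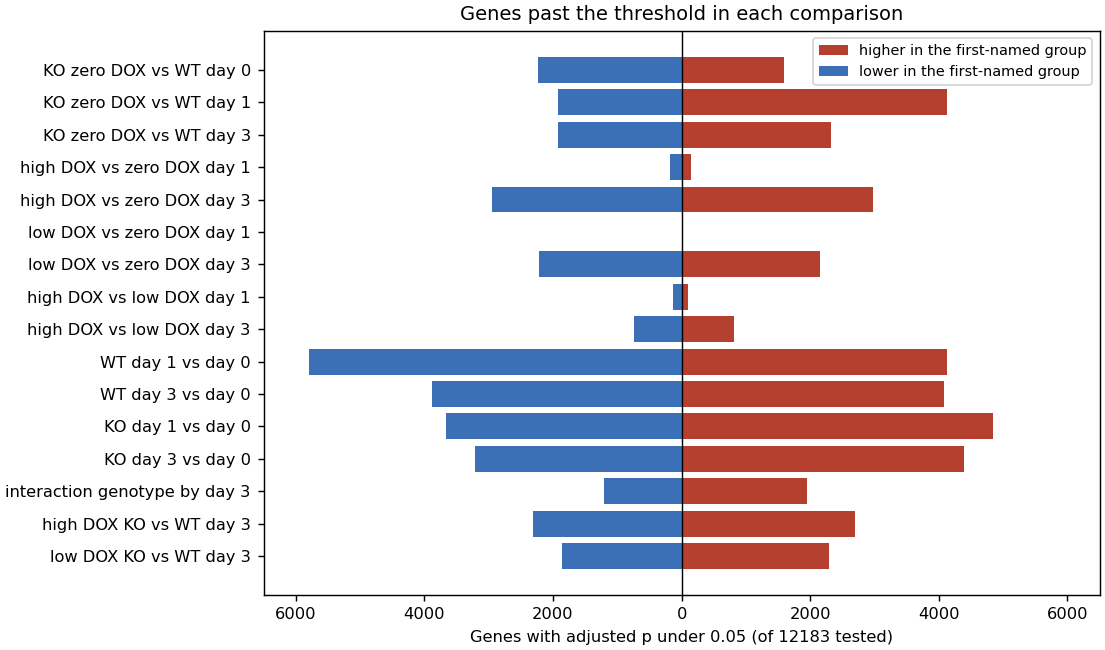
Numbers of genes called changed (limma, adjusted p under 0.05) in each comparison, with genes higher in the group named first on one side and genes lower on the other. The largest total belongs to stimulation of wild-type cells for 1 day (9932 genes), the most higher genes to KO cells at day 1 against day 0 (4844), and low against zero DOX at day 1 has none.

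Irf4 itself was read by a pair of probe sets that behaved differently. The first followed doxycycline: in KO cells at day 3 it stood at 7.50 ± 0.17 (SD, n = 3) on the log2 scale with zero DOX, 13.01 ± 0.076 with low DOX and 13.58 ± 0.068 with high DOX. At day 1 it stood at 12.88 ± 0.21 with high DOX. In wild-type cells, which carry an intact Irf4 gene, it read 8.03 ± 0.061 at day 0 and 7.32 ± 0.081 at day 3, close to the KO cells without doxycycline (8.00 ± 0.19 at day 0). In wild type at day 1 it read 7.82 ± 0.15. This set tracked doxycycline and did not separate the genotypes.

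At day 1 a pair of arrays went against their labels by this probe set. The array labelled zero DOX replicate 2 read 10.77, while its group's other arrays read 7.84 and 7.80. The array labelled low DOX replicate 2 read 7.69, while its group's other arrays read 11.17 and 10.89. The day 1 comparisons that use them are given with the labels as deposited, and each count was also made without them.

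The second probe set had the higher mean and represents Irf4 in the gene counts. In wild type it read 13.17 ± 0.043, 11.72 ± 0.053 and 10.82 ± 0.052 at days 0, 1 and 3, and in KO cells without doxycycline 12.65 ± 0.20 at day 0 and 12.05 ± 0.13 at day 1. It did not respond to doxycycline at day 3 (11.10 ± 0.29 with zero DOX, 11.17 ± 0.25 with low and 11.19 ± 0.17 with high). It was lower in KO than in wild type at day 0 (log2 difference -0.53, adjusted p = 0.003), higher at day 1 (0.33, adjusted p = 0.037, lost without any of 4 arrays at 0.26 to 0.35) and not called at day 3 (0.28, adjusted p = 0.099). A signal of this height in Irf4-/- cells means that this set checks neither genotype. Which part of the transcript each set covers was not analysed here.

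**Figure D2:**
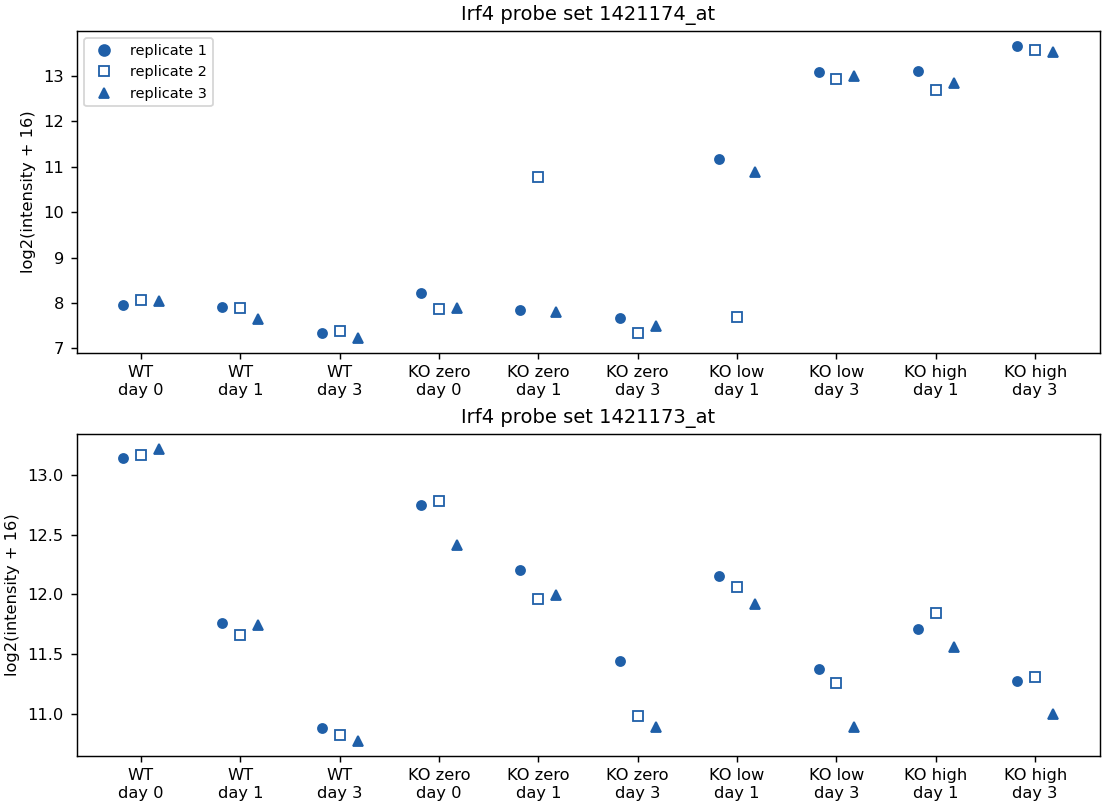
Log2 intensity of both Irf4 probe sets on each of the 30 arrays, by group, with points for single arrays. The first probe set rises with doxycycline except on the array labelled low DOX day 1 replicate 2 (7.69), and it is high on the array labelled zero DOX day 1 replicate 2 (10.77).

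The course of normal activation was described first in wild-type cells. After 3 days of stimulation, genes of cell division and sterol synthesis had risen and the immediate early genes of freshly isolated cells had fallen. The largest rises were in Iigp1, an interferon-inducible GTPase (log2 difference 6.19, SE 0.23, n = 3 per group), Serpinb6b (4.28), Crhbp (4.27), Klhdc2 (4.27), Eaf2, a transcription elongation factor partner (4.23), Tanc2 (4.18), Parm1 (4.15), Ncapg, a condensin subunit (4.14), Ryr2 (3.94) and Pole2, a DNA polymerase subunit (3.87). The largest falls were in Fos (-5.95, SE 0.23), Klf4 (-5.93), Nr4a1 (-5.52), Plk2 (-5.36), Rhob (-4.95), Atf3 (-4.88), Fosb (-4.57), Hes1 (-4.35), Ppp1r15a (-4.34) and Rasgef1b (-4.33). In all, 7960 genes changed, 4074 up and 3886 down, of which 781 and 540 changed at least 2-fold. The Irf4 probe set that represents the gene fell by 2.35. This set also read high in Irf4-/- cells, where it changed by -1.54 over the same days without doxycycline. Its fall therefore cannot be read as a fall of intact Irf4 transcript.

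Among the fixed lists, 31 of 33 cell cycle genes rose and 1 fell (median 2.49, adjusted p = 2.1e-12; adjusted p = 0.14 with an estimated correlation), among them Bub1 (3.69), Cdc6 (3.53) and Mki67, the proliferation marker (3.20). All 20 cholesterol synthesis genes rose (median 2.15, adjusted p = 2.4e-12; adjusted p = 0.14 with an estimated correlation), led by Fdps (3.22) and Mvd (3.00). All 14 immediate early genes fell (median -3.32, adjusted p = 1.1e-10, held with an estimated correlation). Of 30 oxidative phosphorylation genes 27 rose, and of 14 glycolysis genes 10 rose and 2 fell, including Aldoc (2.67) and Tpi1 (2.01); both lists had adjusted p = 0.14 with an estimated correlation. Plasma cell genes rose in 15 of 21 cases and fell in 2 (median 0.76, adjusted p = 0.0016; adjusted p = 0.23 with an estimated correlation), with Prdm1, the regulator of plasma cell differentiation, at 1.35 and Xbp1, the regulator of secretion, at 1.31. Fkbp11 rose by 1.62 in that list while another of its probe sets fell. Secretory pathway genes rose in 31 of 37 cases (adjusted p = 0.15 with an estimated correlation), and 17 of 22 interferon response genes rose with none falling (median 1.23, adjusted p = 4.8e-05; adjusted p = 0.33 with an estimated correlation). Of 23 class switch and repair genes 17 rose and 3 fell (adjusted p = 0.14 with an estimated correlation), led by Exo1 (3.38).

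Genes of resting B cells fell over the same 3 days. Of 9 follicular and recirculation genes 8 fell, including the homing receptor Ccr7 (-2.84) and its regulator Klf2 (-2.15), and the marginal zone markers fell in 5 of 8 cases, led by Cr2 (-3.60). B cell identity genes fell in 14 of 24 cases and rose in 4. With an estimated correlation these lists had adjusted p of 0.14, 0.14 and 0.27. T cell markers fell in 8 of 9 cases (median -0.55; adjusted p = 0.14 with an estimated correlation) beside the resting B cell genes, while myeloid (2 higher, 6 lower of 16, adjusted p = 0.27) and NK markers (1 higher, 2 lower of 9, adjusted p = 0.55) did not pass as lists. NF-kB and CD40 response genes went both ways, with 6 higher and 13 lower of 20 (adjusted p = 0.18 with an estimated correlation). Adjusted over the list alone, 31 of 33 cell cycle genes rose, 15 of 21 plasma cell genes rose, and 9 of 9 T cell markers fell.

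After 1 day 9932 genes had changed in wild-type cells, 4133 up and 5799 down. Ccl22, a chemokine of CD40-activated B cells, rose most (6.75, SE 0.33), followed by Socs2 (4.40, with 1 of its 4 other probe sets falling), Cdc6 (4.18), Exo1 (4.17) and Dhrs3 (4.15). Fos (-6.79), Plk2 (-5.85), Irs2 (-5.66), Klf4 (-5.61) and Nr4a1 (-5.47) fell most. All 25 ribosome biogenesis genes rose (median 1.27, adjusted p = 6.9e-12; adjusted p = 0.14 with an estimated correlation), Nop16 most (2.47). Markers of other spleen cells fell over the same day: 9 of 9 T cell (median -0.78, adjusted p = 0.0073; adjusted p = 0.19 with an estimated correlation), 7 of 9 NK (median -0.85, list adjusted p = 0.21) and 10 of 16 myeloid markers (median -0.58, list adjusted p = 0.21). The median of all genes lay at -0.15 and moved by 0.16 when arrays were centred on their medians and by 0.11 with quantile normalization. Centring turned the split from 41.6% to 52.3% higher genes (4963 higher and 4532 lower of 9495).

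In KO cells without doxycycline, stimulation changed 8508 genes by day 1 (4844 up, 3664 down) and 7600 by day 3 (4385 up, 3215 down). The day 1 group holds the array labelled zero DOX replicate 2, which went against its label, and 8092 genes were called without it. At day 1 the largest rises were in Ccl22 (5.43), Iigp1 (5.06), Usp18 (4.87), Ifit1 (4.59) and Socs1 (4.44), of which Usp18 and Ifit1 are interferon-induced and Socs1 restrains cytokine signalling. At day 3 they were in Iigp1 (6.57), the interferon-induced GTPase Gbp2b (5.46), Socs1 (4.61), Usp18 (4.56) and Gng12 (4.24). Fos fell most on both days (-6.30 and -5.92). All 22 interferon response genes rose by day 3 (median 2.37, adjusted p = 2.3e-10; adjusted p = 0.25 with an estimated correlation), 31 of 33 cell cycle genes rose (median 1.96; adjusted p = 0.31 with an estimated correlation) and 19 of 20 cholesterol synthesis genes rose (median 1.38; adjusted p = 0.25 with an estimated correlation). By day 1, 10 of 16 myeloid (median -1.11; adjusted p = 0.44 with an estimated correlation), 8 of 9 NK (median -1.32; adjusted p = 0.32 with an estimated correlation) and 7 of 9 T cell markers (median -0.32; adjusted p = 0.19 with an estimated correlation) had fallen. By day 3, T cell markers were lower in 7 of 9 cases and higher in 1 (list adjusted p = 0.061), and myeloid (adjusted p = 0.18) and NK markers (0.78) did not pass either.

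Before stimulation, KO B cells already differed from wild type in 3832 genes, 1592 higher and 2240 lower. Sex and marker transcripts of other spleen cells differed between the genotypes here as well, so this cannot be read as a difference of Irf4 alone. Jchain, the joining chain of secreted IgM and IgA, was lowest of the called genes (log2 difference -7.05, SE 0.31, n = 3 per group), followed by Crisp3 (-4.31), Kctd14 (-3.42), Trim34a (-2.81) and Sdc1, the plasma cell surface proteoglycan (-2.78). Xaf1, an interferon-inducible gene, was highest (3.59, although its other probe set fell), then Slc12a5 (3.49), Adgrl2 (3.23), Mdm1 (2.55) and Lyz1, a lysozyme of myeloid cells (2.53). The Trim34a call rested on KO arrays that varied widely (SD 2.1), its other probe set moved the other way, and it was no longer called without KO day 0 replicate 2 (-1.61) or without any 1 wild-type array (-2.79 to -2.81). The immunoglobulin constant region genes all fell (3 of 3, median -1.89, adjusted p = 4.1e-05, held with an estimated correlation): Ighg3 by -2.62, Igha by -1.89 and Ighm by -0.57. Pax5, a keeper of B cell identity, was higher (0.45), and Bcl6, the germinal centre repressor, lower (-1.09).

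Markers of other spleen cells were higher in the KO day 0 samples. Of 16 myeloid markers 13 were higher (median 1.42, adjusted p = 1.2e-09; adjusted p = 0.17 with an estimated correlation), including Lyz1 and Mpo (2.41), and 5 of 9 NK markers were (median 0.68, adjusted p = 7.5e-05; adjusted p = 0.25 with an estimated correlation). Of 33 cell cycle genes 21 were higher (median 0.35; adjusted p = 0.41 with an estimated correlation), of 25 ribosome biogenesis genes 9 were higher and 1 lower (adjusted p = 0.41 with an estimated correlation), and of 20 NF-kB and CD40 response genes 7 were higher and 1 lower (adjusted p = 0.21 with an estimated correlation). The interferon response list did not stand apart (5 higher, 6 lower of 22, median -0.157, adjusted p = 0.69). Fitted on these 6 arrays alone, 1332 genes were called, and KO replicates 1 and 2 came from males while every wild-type array came from a female; with a sex term 3410 genes were called, 2993 of them shared. Without KO day 0 replicate 2, whose Gapdh control stood apart, 2803 were called, and 4527 without KO day 0 replicate 3, the array of lowest weight. Centring gave 1618 higher and 1617 lower genes.

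After 1 day the KO cells without doxycycline differed from wild type in 6048 genes, 4131 higher and 1917 lower. This comparison holds the array labelled zero DOX replicate 2, which went against its label by the first Irf4 probe set. With 1 array left out in turn, counts ran from 4813 to 5794. KO replicates 1 and 2 came from males and every wild-type array from a female. With a sex term 6609 genes were called, 5543 of them shared in the same direction. Interferon-induced genes led those that were higher: Xaf1 (5.43, SE 0.26), Parp12 (3.31), Ifi207 (3.27) and Ifi204 (3.02), together with the transcription factor Maf (3.40). Xaf1 had already stood 3.59 higher at day 0, when the interferon response list did not stand apart. Jchain (-4.16), Crisp3 (-4.09), Havcr1 (-2.53), Gad1 (-2.21) and Nebl (-2.05) were lowest. Of 22 interferon response genes 21 were higher (median 1.95, adjusted p = 1.6e-16; adjusted p = 0.26 with an estimated correlation), including Ifit1 (2.55), Oasl2 (2.52) and Ifit3 (2.44). Myeloid markers were higher beside them in 15 of 16 cases (median 0.909; adjusted p = 0.46 with an estimated correlation) and T cell markers in 7 of 9 (median 0.535; adjusted p = 0.26 with an estimated correlation). NK (5 of 9, median 0.541, list adjusted p = 0.30), dendritic (5 of 7, median 0.394, 0.18) and erythroid markers (2 of 3, median 0.466, 0.38) were also higher, with none lower. Ribosome biogenesis genes fell in 13 of 25 cases with none rising (median -0.16, adjusted p = 1.1e-05; adjusted p = 0.41 with an estimated correlation).

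Smaller shares of other lists were lower at day 1: 9 of 21 plasma cell genes (3 higher; adjusted p = 0.46 with an estimated correlation), 9 of 20 cholesterol synthesis genes (2 higher; adjusted p = 0.66 with an estimated correlation), 9 of 23 class switch and repair genes (3 higher; adjusted p = 0.34 with an estimated correlation), 7 of 21 germinal centre genes (1 higher; adjusted p = 0.34 with an estimated correlation) and 8 of 37 secretory genes (3 higher; adjusted p = 0.70 with an estimated correlation). The median of all genes lay at 0.073 and moved by -0.14 when arrays were centred, which turned the share of higher genes from 68.3% to 38.1% (2410 higher and 3912 lower of 6322). With the stricter filter 3560 genes were called.

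At day 3, when wild-type cultures contained plasma cell transcripts, KO cells without doxycycline had low plasma cell transcripts and, among the most changed genes, high interferon-induced and myeloid transcripts. As lists, the latter were not called with an estimated correlation (adjusted p = 0.081 and 0.16). Jchain was lowest (log2 difference -6.90, SE 0.31, adjusted p = 7.9e-14, n = 3 per group), followed by Crisp3 (-5.34), Bhlha15, a transcription factor of secretory cells (-3.15), Fam171a1 (-2.77), the protease inhibitor Slpi (-2.72), Pon3 (-2.68), the DNA glycosylase Neil1 (-2.49), Rgs10 (-2.40), Sdc1 (-2.33) and Pinlyp (-2.30). The highest were Xaf1 (4.56, SE 0.26; its other probe set read -0.39 and was not called), Lyz1 (4.52), the chemokine Ccl6 (4.08), the chitinase-like Chil3 (3.93), Gbp2b (3.68), Maf (3.62), the beta-glucan receptor Clec7a (3.52), Lyz2 (3.45), the interferon-inducible Ifi207 (3.15) and Alox5ap, of leukotriene synthesis (3.03). In all 4247 genes changed, 2318 higher and 1929 lower, 220 and 114 of them at least 2-fold. Quantile normalization turned this split to 2043 higher and 2331 lower (54.6% to 46.7% higher).

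Of 21 plasma cell genes 17 were lower and none higher (median -1.37, adjusted p = 6.9e-17, and 0.0046 with an estimated correlation; 17 also adjusted over the list alone). Prdm1 was lower by -1.70 (SE 0.20, adjusted p = 4.8e-07) and Xbp1 by -0.72. Of 37 secretory pathway genes 29 were lower and 1 higher (median -0.42, adjusted p = 1.1e-15; adjusted p = 0.064 with an estimated correlation; 30 lower adjusted over the list alone), led by the COPII coat gene Sec24d (-1.86) and the chaperone Hyou1 (-0.83). Of 20 cholesterol synthesis genes 18 were lower and none higher (median -0.67, adjusted p = 9.9e-13; adjusted p = 0.081 with an estimated correlation), including Sqle (-1.03), Lss (-1.02) and Nsdhl (-0.99). Germinal centre genes were lower in 8 of 21 cases and higher in 2 (adjusted p = 0.0088; adjusted p = 0.12 with an estimated correlation), with Neil1, Mybl1 (-2.17) and Gcsam (-2.15) moving most, and glycolysis genes were lower in 7 of 14 cases and higher in 2 (adjusted p = 0.013; adjusted p = 0.16 with an estimated correlation), led by Aldoc (-1.36).

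Interferon response genes were higher in 21 of 22 cases, the same number adjusted over the list alone (median 1.26, adjusted p = 1.1e-15; adjusted p = 0.081 with an estimated correlation), with Ifit3 at 2.78, Ifit1 at 1.99 and Irf7, the interferon-induced transcription factor, at 1.95. Beside them, 12 of 16 myeloid markers (median 1.30; adjusted p = 0.16 with an estimated correlation), 7 of 9 NK markers (median 1.02, with the granzyme Gzma at 2.28; adjusted p = 0.16 with an estimated correlation) and 4 of 9 T cell markers (median 0.13; adjusted p = 0.16 with an estimated correlation) were higher and none lower. NF-kB and CD40 response genes were higher in 13 of 20 cases and in 15 adjusted over the list alone (median 0.55, adjusted p = 2.9e-08, and 0.0046 with an estimated correlation), led by Ccl22 (2.27), Ccl3 (1.04) and Traf1 (1.01). The interferon regulatory factors and their partners were higher in 13 of 17 cases and lower in 1 (median 0.34; adjusted p = 0.064 with an estimated correlation), Spib by 0.63 and Irf8 by 0.23, and Pax5 was higher by 0.51. Bcl6 (-0.31, adjusted p = 0.27) and Bach2 (-0.11, adjusted p = 0.57) were not called.

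The other lists did not pass between KO and wild type at day 3. None of 13 MHC class II genes was called (adjusted p = 0.70), and of 24 B cell identity genes 7 were higher and 3 lower (adjusted p = 0.16), among them Syk (1.37) and Cd72 (1.10). Of 33 cell cycle genes 1 was higher and 6 lower (adjusted p = 0.16). The adjusted p was 0.21 for apoptosis regulators, 0.16 for class switch and repair genes, 0.81 for dendritic, 0.42 for erythroid and 0.12 for marginal zone markers, 0.16 for follicular genes, 0.11 for immediate early genes, 0.11 for immunoglobulin constant regions, 0.11 for oxidative phosphorylation and 0.16 for ribosome biogenesis. With a sex term 4393 genes were called, of which 3678 were called in the same direction without it.

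**Figure D3:**
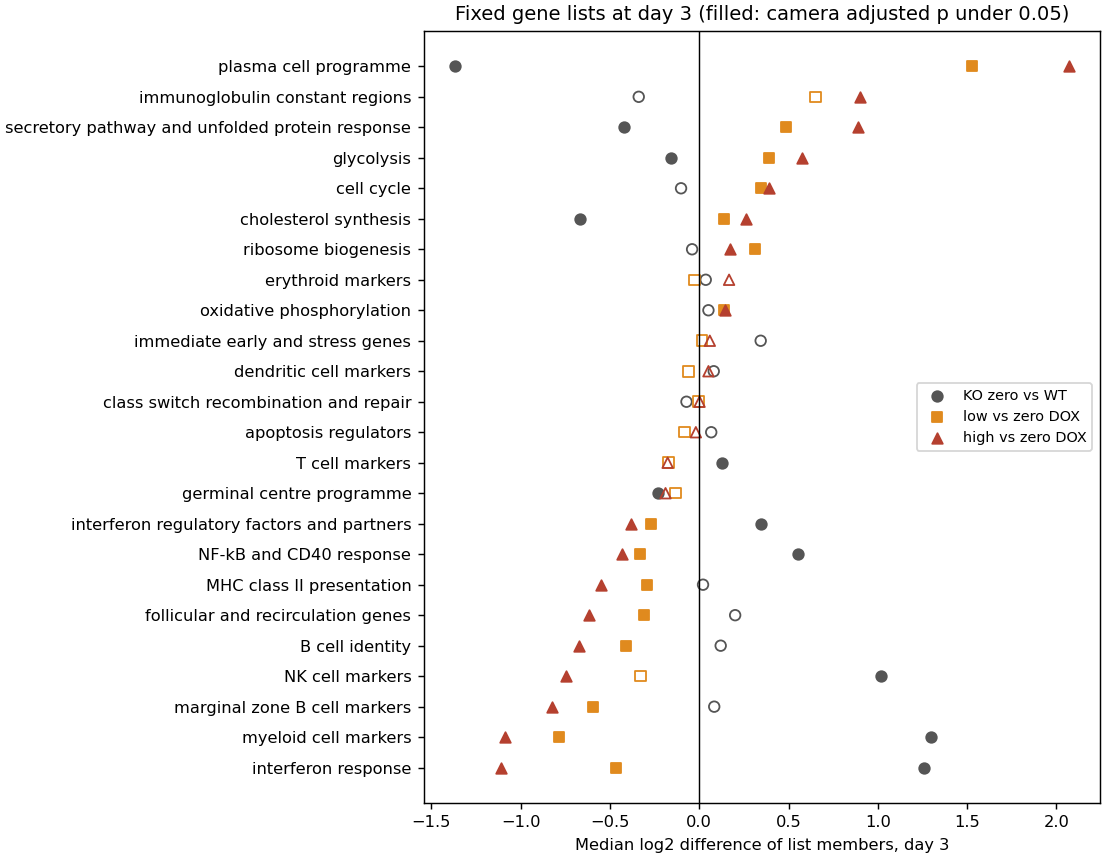
Median log2 difference of each fixed gene list at day 3, 1 point per list and comparison. The comparisons are KO zero DOX against wild type, low against zero DOX, and high against zero DOX. Plasma cell genes lie at -1.37 for KO zero DOX against wild type and at 2.07 for high against zero DOX. Interferon response genes lie at 1.26 and -1.11 in these comparisons.

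The change from day 0 to day 3 itself differed between the genotypes for 3156 genes, with KO minus wild type positive in 1944 and negative in 1212, whether the gene rose or fell. Fitted on these arrays alone 1953 were called, 2705 without KO day 0 replicate 2 and 3757 without KO day 0 replicate 3. Gbp2b (3.56, SE 0.27), Mmp12 (3.19), Ifit3 (3.19), Ighg3 (2.91) and Ifit1bl1 (2.80) gained more in KO cells, and the difference was most negative for Slc12a5 (-3.44), Bhlha15 (-3.11), Cd5l (-2.82), Slpi (-2.82) and Mdm1 (-2.58), which all fell in KO cells. For Prdm1 it was -1.95, while Sdc1 did not pass (0.45, adjusted p = 0.13). The Cd5l call was lost without KO day 0 replicate 1 (-2.30) or replicate 2 (-2.02). Slc12a5 and Mdm1 had already stood higher in KO than in wild-type cells at day 0, and Ighg3 lower, by about the size of their differences. For these genes the difference thus comes mostly from day 0. The gene lists of this interaction and the sizes of their shifts are among the additional observations.

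Doxycycline at the high dose changed 5923 genes at day 3, 2972 up and 2951 down. The labels give no doxycycline dose for cells without the inducible gene. Effects of the drug itself therefore cannot be told apart from those of restored Irf4 in any comparison of doses. Jchain rose most (log2 difference 6.93, SE 0.31, adjusted p = 1.7e-14, n = 3 per group), from 6.55 ± 0.33 to 13.49 ± 0.16, then Bhlha15 (4.68), the adhesion molecule Epcam (4.59), Klrb1f (4.28), Slpi (4.09), Pon3 (3.96), Rhpn2 (3.93), Mpzl2 (3.90), Tg (3.33) and Rgcc (3.25). The platelet chemokine Pf4 (-4.52, SE 0.29), Lyz1 (-4.46), Chil3 (-4.42), the platelet gene Ppbp (-4.17), Gbp2b (-3.82), Ccl6 (-3.40), Lyz2 (-3.34), Ifitm1 (-3.13), the interferon gene Ifng (-3.10) and the neutrophil gene S100a9 (-3.08) fell most. At least 2-fold changes numbered 281 up and 310 down. Centring gave 2667 up and 2974 down.

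Of 21 plasma cell genes 20 rose and 1 fell (median 2.07, adjusted p = 3.9e-15, and 0.017 with an estimated correlation; the same counts adjusted over the list alone), Prdm1 by 3.20 (SE 0.20), Fkbp11 by 3.00 and Sdc1 by 2.99. Of 37 secretory pathway genes 36 rose and 1 fell (median 0.89, adjusted p = 5e-23, and 0.026 with an estimated correlation), with Sec24d at 3.16, Edem2 at 1.62 and Hyou1 at 1.56, and Xbp1 rose by 0.94. Glycolysis genes rose in 12 of 14 cases (median 0.58, adjusted p = 3.5e-06, and 0.031 with an estimated correlation), including Aldoc (1.64), Hk2 (1.28) and Pfkl (1.07). Cell cycle genes rose in 18 of 33 cases with none falling (median 0.39; adjusted p = 0.40 with an estimated correlation), oxidative phosphorylation genes in 16 of 30 (adjusted p = 0.25 with an estimated correlation), ribosome biogenesis genes in 13 of 25 (adjusted p = 0.44 with an estimated correlation) and cholesterol synthesis genes in 11 of 20, with 1 falling (adjusted p = 0.44 with an estimated correlation). Of the immunoglobulin constant regions, Ighg3 (1.40) and Ighm (0.90) rose (list adjusted p = 0.048; adjusted p = 0.13 with an estimated correlation, and 0.062 with the replicate block).

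B cell genes fell in the same cultures. Of 24 B cell identity genes 20 fell and 3 rose (median -0.67, adjusted p = 3.5e-06; adjusted p = 0.13 with an estimated correlation), Cd72 by -1.77, Bcl11a by -1.26 and Pax5 by -1.12. Of 13 MHC class II genes 12 fell and 1 rose (median -0.55; adjusted p = 0.18 with an estimated correlation), the transactivator Ciita by -1.53. Bcl6 (-1.42), Spib (-1.03), Spi1 (-0.67) and Irf8 (-0.63) fell, and 14 of 17 interferon regulatory factors and partners fell in all (adjusted p = 1.1e-05, and 0.034 with an estimated correlation). Follicular genes fell in 7 of 9 cases and marginal zone markers in 5 of 8, both with adjusted p = 0.13 with an estimated correlation. NF-kB and CD40 response genes fell in 13 of 20 cases and rose in 2 (adjusted p = 0.07 with an estimated correlation). Bach2 did not pass (0.01, adjusted p = 0.96).

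Interferon response genes fell in 21 of 22 cases (median -1.11, adjusted p = 1.7e-07; adjusted p = 0.20 with an estimated correlation), Ifih1 by -1.80, Gbp2 by -1.65 and Ifit2 by -1.61. Myeloid markers fell with them in 12 of 16 cases (median -1.09; adjusted p = 0.21 with an estimated correlation) and NK markers in 8 of 9 (median -0.75; adjusted p = 0.18 with an estimated correlation), Gzma by -2.93. The germinal centre list did not pass (4 up, 9 down, adjusted p = 0.096), nor did T cell markers (adjusted p = 0.096), apoptosis (0.42), class switch (0.89) and immediate early genes (0.64) or dendritic (0.89) and erythroid markers (0.42).

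**Figure D4:**
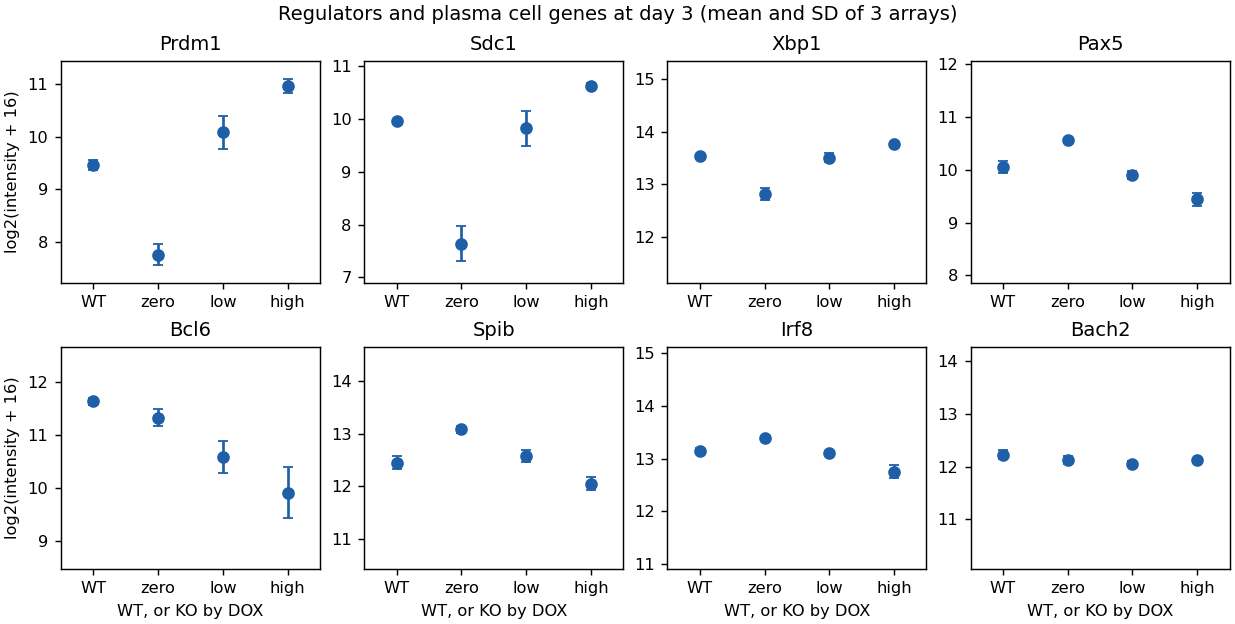
Log2 intensity at day 3 of Prdm1, Sdc1, Xbp1, Pax5, Bcl6, Spib, Irf8 and Bach2 from the fixed panel. Wild type and KO cells with zero, low and high DOX are shown, with points for group means and bars for the SD (n = 3). Prdm1 stands at 7.77, 10.08 and 10.96 with zero, low and high DOX and at 9.47 in wild type.

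With the low dose 4362 genes differed from zero DOX at day 3, 2149 higher and 2213 lower (2235 and 1703 with centring, 2372 and 2031 with quantile normalization). Jchain (6.41, SE 0.31), Epcam (3.72), Bhlha15 (3.68), Klrb1f (3.26) and Rhpn2 (2.93) rose most, and Chil3 (-3.11), S100a9 (-2.94), S100a8 (-2.74), Pf4 (-2.70) and Ppbp (-2.40) fell most. Plasma cell genes rose in 18 of 21 cases, and in 20 adjusted over the list alone (median 1.53, adjusted p = 3.8e-18, and 0.007 with an estimated correlation), with Prdm1 at 2.31 and Sdc1 at 2.19. Secretory genes rose in 33 of 37 cases (median 0.49, adjusted p = 7.9e-25, and 0.019 with an estimated correlation). Ribosome biogenesis genes rose in 21 of 25 cases (median 0.31, adjusted p = 2.6e-10; adjusted p = 0.13 with an estimated correlation), led by Nolc1 (0.58) and Rrp12 (0.56). Cell cycle genes rose in 16 of 33 cases (adjusted p = 0.29 with an estimated correlation). Interferon response genes fell in 14 of 22 cases (median -0.47; adjusted p = 0.35 with an estimated correlation) and myeloid markers beside them in 10 of 16 (median -0.79; adjusted p = 0.23 with an estimated correlation). Pax5 fell by -0.66 and Bcl6 by -0.75.

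Between the doses, 1557 genes differed at day 3, 815 higher with the high dose and 742 lower. The first Irf4 probe set read 13.53 to 13.66 on the high DOX arrays and 12.94 to 13.09 on the low DOX arrays, without overlap. Its difference of 0.58 was not called (SE 0.63, adjusted p = 0.66). That SE takes in the spread of the day 1 low and zero DOX groups (SD 1.9 and 1.7). It therefore does not measure the spread at day 3. The second set, which did not respond to doxycycline at day 3, differed by 0.02 (adjusted p = 0.96). Higher with the high dose were Slpi (log2 difference 1.84, SE 0.43), Rgcc (1.58), Pon3 (1.53), Fnbp1l (1.45), Mpzl2 (1.42), Nmb (1.35), the endoplasmic reticulum protein Ckap4 (1.26), Aldoc (1.25), the peptidyl-prolyl isomerase Fkbp11 (1.17) and Tktl1 (1.14). Lower were Lyz1 (-2.83, SE 0.43), Ccl6 (-2.14), the granzymes Gzma (-2.07) and Gzmb (-2.04), Ifitm1 (-1.94), Gbp2b (-1.93), Pf4 (-1.82), Nkg7, of cytotoxic granules (-1.81), Lyz2 (-1.79) and Ppbp (-1.77). Slpi was no longer called without low DOX replicate 3 (1.44), and Rgcc without any of 5 of the 6 arrays (1.36 to 1.70).

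Plasma cell genes were higher with the high dose in 12 of 21 cases and lower in none (median 0.52, adjusted p = 1.6e-11, and 0.048 with an estimated correlation; 16 higher and 1 lower adjusted over the list alone), with Prdm1 at 0.88 (SE 0.20), Sdc1 at 0.81 and the BCMA gene Tnfrsf17 at 1.11. Secretory genes were higher in 26 of 37 cases, and in 31 adjusted over the list alone (median 0.27, adjusted p = 9e-20, and 0.048 with an estimated correlation). Glycolysis genes were higher in 5 of 14 cases (adjusted p = 7.1e-05; adjusted p = 0.056 with an estimated correlation). B cell identity genes were lower in 10 of 24 cases (median -0.23; adjusted p = 0.10 with an estimated correlation) and MHC class II genes in 9 of 13 (median -0.26; adjusted p = 0.12 with an estimated correlation), including Pax5 (-0.46), Spib (-0.53) and Ciita (-0.84). Ribosome biogenesis genes were lower in 8 of 25 cases (median -0.13; adjusted p = 0.15 with an estimated correlation), follicular genes in 5 of 9, and no cell cycle gene was called (adjusted p = 0.78).

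Interferon response genes were lower with the high dose in 12 of 22 cases (median -0.58, adjusted p = 2.7e-09; adjusted p = 0.15 with an estimated correlation), NK markers beside them in 6 of 9 (median -0.98; adjusted p = 0.056 with an estimated correlation) and myeloid markers in 3 of 16 (adjusted p = 0.024; adjusted p = 0.44 with an estimated correlation). The count fell to 868 without high DOX replicate 1, to 983 without low DOX replicate 3 and to 695 with these 6 arrays alone, and rose to 4019 with array weights. Centring on array medians moved the share of higher genes from 52.3% to 36.0% (512 higher and 910 lower of 1422).

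Across the 3 doses at day 3, 541 genes rose at both steps and 581 fell at both. In 56 genes the low dose lay apart from both other doses in the same direction, 37 of them highest and 19 lowest at low DOX. These 56 fell to 34, 24 and 37 without high DOX replicates 1, 2 and 3, and to 28 and 37 without low DOX replicates 1 and 2. A replicate block within genotype gave 113, these arrays alone 27 and array weights 335. Centring gave 44, of which 42 were highest and 2 lowest at low DOX (95.5% highest, against 66.1%).

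At day 1 doxycycline had done less. Against zero DOX, the high dose changed 335 genes, 153 up and 182 down. Fitted on the compared arrays alone it was 3 genes, and with centring 190, with 53.2% of them up against 45.7%. Socs2, a feedback inhibitor of cytokine signalling (1.40, SE 0.19), Eaf2 (1.27), Gpr155 (1.07), the scavenger receptor Cd36 (1.03) and Sdc1 (1.01) rose most, and Ifng (-1.72), Maf (-1.48), Chil3 (-1.47), Mpo (-1.18) and Il15 (-1.0) fell most. Of 21 plasma cell genes 4 rose, and 6 adjusted over the list alone (median 0.20, adjusted p = 2.1e-06; adjusted p = 0.15 with an estimated correlation). Of 22 interferon response genes 8 fell, and 16 adjusted over the list alone (median -0.49, adjusted p = 1.1e-18; adjusted p = 0.13 with an estimated correlation), with 1 of 16 myeloid markers beside them (median -0.22; adjusted p = 0.30 with an estimated correlation). As list means, myeloid markers went from 8.681 with zero DOX to 8.175 with high DOX, and interferon response genes from 12.04 to 11.54. Irf8 fell by -0.38.

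This day 1 count moved with single arrays: it was 87 and 138 without high DOX replicates 1 and 3, 109 without zero DOX replicate 1 and 202 without the array labelled zero DOX replicate 2. Without both arrays of doubtful label it was 208, and with the replicate block, which the pairing of KO arrays calls for, it was 511, or 673 with the block within genotype. Array weights gave 687. The Chil3 call was lost without any of 5 arrays (-1.04 to -1.65) and the Il15 call without any of 4 (-0.71 to -1.11). High against low DOX at day 1 gave 227 genes, 98 higher and 129 lower, with Socs2 (1.34), Eaf2 (1.30), Cd36 (1.01), Gpr155 (0.95) and Sdc1 (0.95) higher and Ifng (-1.77), Maf (-1.33), Mpo (-1.28), Calhm6 (-0.93) and Il15 (-0.93) lower. Of these, Ifng was no longer called without the array labelled low DOX replicate 2 (-1.50), Gpr155 without any of 3 arrays (0.73 to 0.94) and Il15 without any of 4 (-0.63 to -1.04). That count was 73 and 84 without high DOX replicates 1 and 3, 130 without low DOX replicate 1, 72 without the array labelled low DOX replicate 2, 0 on the compared arrays alone, 145 with centring, 69 without both doubtful arrays, 359 with the replicate block and 504 with the block within genotype. Low against zero DOX at day 1 gave 0 genes in limma, with 34 at an unadjusted p under 0.05, a smallest adjusted p of 1, and 0 also with the replicate block, array weights and every other alternative that was run. The 34 are far fewer than the share of 0.05 of the 12183 genes that a calibrated test gives among unchanged genes. The main fit leaves out the pairing of the KO arrays, whose same-numbered deviations correlated at 0.71, 0.51 and 0.65 between these groups. The test was thus conservative here, and 0 calls do not show that no gene changed. This comparison holds both arrays that went against their labels.

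Cells with restored Irf4 were also set against wild type at day 3, to see how far they approached it. With the high dose 5008 genes differed, 2695 higher and 2313 lower. Klrb1f (4.59, SE 0.12), Xaf1 (3.92), Epcam (3.40), Egln3 (3.35) and Phlda1 (3.32) were highest, and Crisp3 (-4.17), Crhbp (-3.22), Parm1 (-3.18), Hemgn (-3.12) and Ryr2 (-2.92) lowest. Prdm1 (1.50) and Sdc1 (0.66) exceeded wild type, and Bcl6 (-1.73) and Pax5 (-0.61) were below it. Plasma cell genes exceeded wild type in 16 of 21 cases (median 0.64; adjusted p = 0.18 with an estimated correlation) and secretory genes in 29 of 37 (median 0.44; adjusted p = 0.14 with an estimated correlation), while 13 of 21 germinal centre genes were lower (median -0.65, adjusted p = 2.2e-06, and 0.021 with an estimated correlation) and 15 of 20 cholesterol synthesis genes were lower (median -0.44; adjusted p = 0.37 with an estimated correlation).

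With the low dose 4164 genes differed from wild type, 2298 higher and 1866 lower. Xaf1 (4.17, SE 0.26), Klrb1f (3.57), Lyz1 (2.89), the transcription factor Tbx21 (2.89) and Ccl6 (2.82) were highest, and Crisp3 (-4.65), Parm1 (-2.83), Crhbp (-2.75), Map7 (-2.23) and Hemgn (-2.21) lowest. Prdm1 exceeded wild type (0.61, adjusted p = 0.02), a call lost without low DOX replicate 1 or 2 or wild-type replicate 2 (0.48 to 0.57). Sdc1 was not called (-0.15, adjusted p = 0.49). Interferon response genes were higher in 16 of 22 cases (median 0.74; adjusted p = 0.32 with an estimated correlation), with 6 of 9 NK markers higher beside them (median 1.26; adjusted p = 0.43 with an estimated correlation). Myeloid markers were higher in 7 of 16 cases and lower in 1 (median 0.19, list adjusted p = 0.20). Germinal centre genes were lower in 12 of 21 cases (median -0.40, adjusted p = 9e-06, and 0.034 with an estimated correlation). With a sex term 4876 genes were called for the high dose and 3701 for the low dose, and array weights gave 6868 for the low dose.

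**Figure D5:**
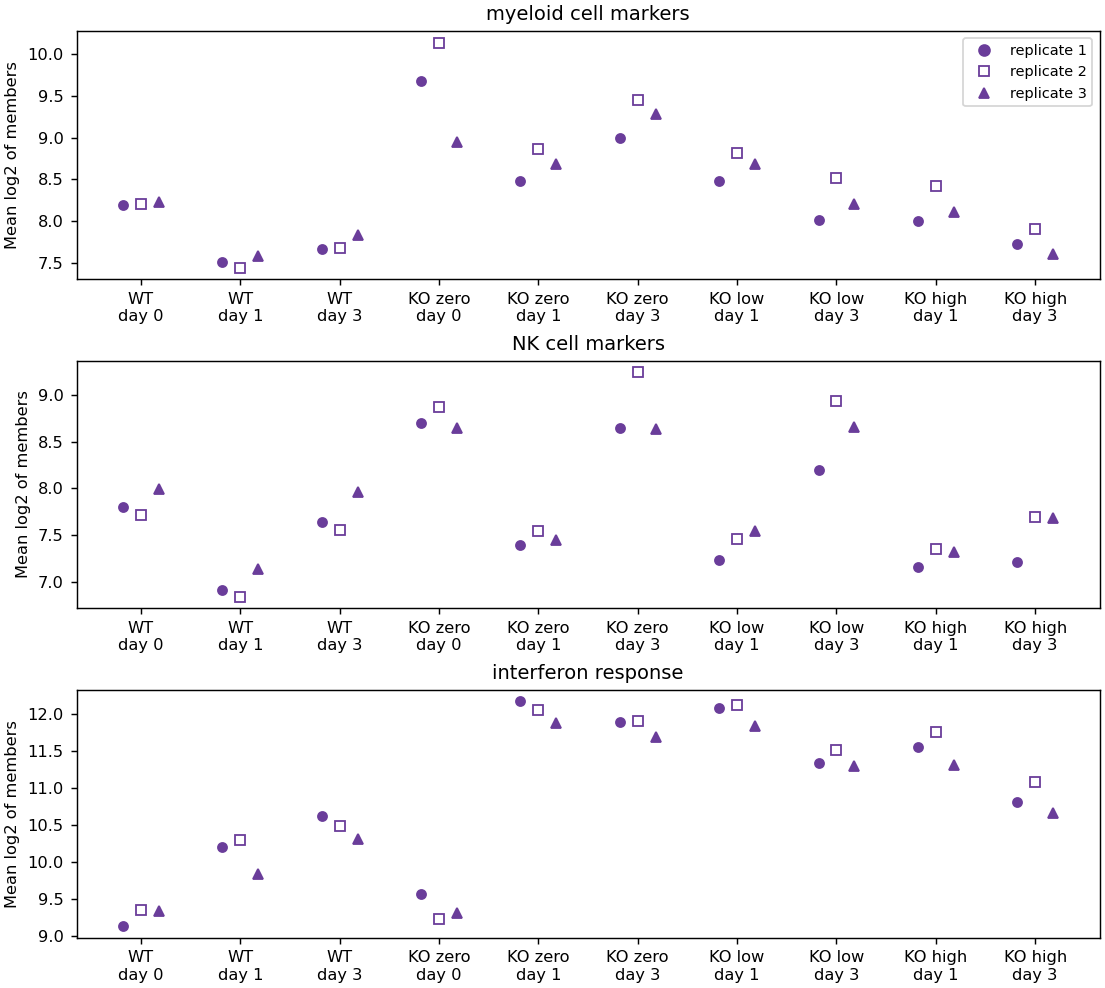
Mean log2 intensity of the interferon response, myeloid and NK lists on each array, by group, with points for single arrays. The interferon list is higher in KO zero DOX than in wild type at days 1 and 3. At day 0 its means lie close together (9.38 ± 0.17 in KO and 9.28 ± 0.12 in wild type, SD). The myeloid list is higher in KO at all 3 days.

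The effects of the high dose (high minus zero DOX, day 3) were compared across genes with the effects of genotype (wild type minus KO zero DOX, day 3). They correlated at r = 0.609 over 12183 genes, which are not independent replicates. Both comparisons share the zero DOX arrays: unchanged groups simulated against shared controls gave a mean r of 0.475 and a highest r of 0.964 over 100 simulations, so the correlation alone does not set a rescue apart from shared arrays. The covariance was 0.119, against a simulated mean of 0.00757 and a highest of 0.0344, a difference of 0.111. In both comparisons 1124 genes were higher and 1426 lower, and 334 genes were called in opposite directions. Unchanged groups simulated against shared controls shared a mean of 2.37 higher and 1.57 lower calls, and at most 159 and 94. Independent lists of these sizes would share 470.6 and 561.5, a value that leaves out the shared arrays as the simulated one leaves out the effects. Splitting the 3 shared arrays would leave 1 part with a single array, so this was not done, and part of the excess may come from the shared arrays.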

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

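The tests of explanations in this part, for the interferon response genes and for the pair of day 1 arrays, were chosen after the results were seen, and the interaction of genotype with day was planned.

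The response to 3 days of stimulation differed between KO and wild-type cells in a test of the difference itself, which called 3156 genes. The change in KO minus that in wild type was negative for plasma cell genes (median -0.631, 14 of 21 lower; adjusted p = 5.9e-11, and adjusted p = 0.078 with an estimated correlation), and also for secretory pathway genes (median -0.355, 23 of 37 lower), cell cycle genes (median -0.518, 19 of 33 lower), cholesterol synthesis genes (median -0.399, 10 of 20 lower), glycolysis genes (median -0.304, 9 of 14 lower) and ribosome biogenesis genes (median -0.216, 10 of 25 lower). It was positive for interferon response genes (median 1.09, 17 of 22 higher, and 21 adjusted over the list alone), the interferon regulatory factors and partners (median 0.248, 9 of 17), NF-kB and CD40 response genes (median 0.344, 11 of 20) and the immunoglobulin constant regions (median 1.55, 2 of 3), which had started lower in KO cells at day 0. Cell cycle and ribosome biogenesis genes had started higher in KO cells (medians 0.353 and 0.142) and lay near wild type at day 3 (-0.102 and -0.0401), so their negative sign comes mostly from day 0. None of these 10 lists passed with an estimated correlation, whose adjusted p ran from 0.078 to 0.28.

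Single genes with such a difference were Gbp2b (3.56), Mmp12 (3.19), Ifit3 (3.19), Ighg3 (2.91) and Ifit1bl1 (2.80), which gained more in KO cells. The difference was negative for Slc12a5 (-3.44), Bhlha15 (-3.11), Cd5l (-2.82), Slpi (-2.82) and Mdm1 (-2.58), all of which fell in KO cells, Cd5l from 10.10 to 6.61 and Bhlha15 from 8.30 to 6.17. The KO day 0 arrays varied widely for Cd5l (SD 2.3), Slc12a5 (SD 1.2) and Slpi (SD 1.1). Slc12a5 and Mdm1 had started higher in KO than in wild-type cells at day 0, and Ighg3 lower, by about the size of these differences. For these genes the difference thus comes mostly from day 0.

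Interferon response genes stood higher in KO cells without doxycycline than in wild type at day 1 (median 1.95; adjusted p = 0.26 with an estimated correlation) and day 3 (median 1.26; adjusted p = 0.081 with an estimated correlation), together with myeloid markers (medians 0.909 and 1.30). RNA of other spleen cells as they were at day 0 is argued against: at day 0 the myeloid median was already 1.42, while the interferon response list stood at -0.157, with quartiles of -0.374 and 0.407 that lie below the lower quartile of 1.39 at day 1. With a sex term the list kept a median of 1.84 at day 1, with 21 of 22 members called. Every wild-type array came from a female, so this term is set by KO replicates 1 and 2 against KO replicate 3. It cannot part sex from other traits of that replicate, so sex is not decided by it. Loss of Irf4 remains a candidate explanation, as the list fell with high DOX at day 3 (median -1.11), but myeloid and NK markers fell with it, and that call had an adjusted p of 0.20 with an estimated correlation. Other spleen cells that were activated in culture therefore stay open beside it.

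The Irf4 probe set that follows doxycycline, which the gene counts do not use, read 10.77 on the array labelled zero DOX day 1 replicate 2, where no signal of the restored gene is due. The other 8 zero DOX arrays read 7.34 to 8.21, so a mere lack of induction in the low DOX culture, whose array read 7.69, would leave this value unaccounted for. An exchange of these 2 arrays is a candidate explanation: over 4362 genes called at day 3, the day 1 low minus zero difference of replicate 2 correlated at -0.225 with the day 3 difference, against 0.406 and 0.161 for replicates 1 and 3. Genes are not independent replicates, no biological explanation was tested, and no array was moved to another group.

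Of 4427 tested probe sets with no single gene name, 1667 passed between high and zero DOX at day 3, 615 higher and 1052 lower.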

How the results depend on the processing

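The fits with a replicate block within genotype, without the arrays labelled day 1 replicate 2 of zero and low DOX, with both changes, and with a sex term were chosen after the data were seen. No call of a named gene or list was reversed in any alternative that was run. Genes that were not named were not checked for this. Testing each probe set on its own kept the same set for a named gene, so it could not reverse a call. Other probe sets of some named genes moved the other way, as stated with those genes. Another scaling turned which direction held more genes in several comparisons, KO against wild type at days 1 and 3 among them. Of 355 alternative counts 305 stayed within 1.5 times the reported one; of 1536 list tests 1253 kept their side of the threshold, 184 lost and 99 gained a call; of 31621 named gene tests 30539 kept theirs, 946 lost and 136 gained one. For the counts that moved, the cause was not tested unless stated.

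Centring arrays gave 190 genes for high against zero DOX at day 1 and 145 for high against low DOX at day 1. The stricter filter, which leaves fewer genes to test, gave 3560 for KO against wild type at day 1. With only the compared arrays, which leaves fewer samples, counts were 1332 for KO against wild type at day 0, 3 and 0 for high against zero and against low DOX at day 1, 695 for high against low DOX at day 3, 1953 for the interaction and 27 for genes with low DOX apart. Array weights gave 687 for high against zero DOX at day 1, 4019 for high against low DOX at day 3, 6868 for low DOX KO against wild type and 335 for low DOX apart. Testing all 26095 probe sets, and so more items, gave 7927, 12159 and 9082 for KO against wild type at days 0, 1 and 3, 11863, 8236 and 2711 for high against zero, low against zero and high against low DOX at day 3, 20914 and 17081 for wild type and 18220 and 16424 for KO at days 1 and 3 against day 0, 6049 for the interaction, and 9766 and 7998 for high and low DOX KO against wild type.

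The replicate block gave 511 genes for high against zero DOX and 359 for high against low DOX at day 1, and the block within genotype gave 673, 504 and, for low DOX apart, 113; it moved no other count by more than 1.5 times. Without both doubtful arrays these day 1 counts were 208 and 69, and with the block within genotype as well, 585 for high against zero DOX and 113 for low DOX apart. With 1 array left out, counts ran from 87 to 349 for high against zero and 72 to 261 for high against low DOX at day 1, from 868 to 1526 for high against low DOX at day 3 and from 24 to 62 for low DOX apart. The correlation of high DOX and genotype effects ran from 0.567 to 0.630 without 1 replicate number. Genes near the array background are compressed by the offset, so their changes are understated.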

Other observations

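The tests of ribosome biogenesis among the genes highest at low DOX, and the tests of explanations for genes apart between KO and wild type throughout, were chosen after the results were seen, as were splits that keep the pairing of the KO arrays; the other counts over splits were planned.

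Some genes of ribosome assembly peaked at the low dose of doxycycline at day 3. Of 37 genes higher at low DOX than at both zero and high DOX, 8 belonged to the fixed ribosome biogenesis list of 25 genes, or 32% of that list against 0.3% of all 12183 genes (one-sided Fisher's exact test p = 3.4e-15, adjusted p = 8e-14 over 24 lists, and no other list passed). The shifts of the whole list had adjusted p of 0.13 for low against zero DOX and 0.15 for high against low DOX with an estimated correlation, and were not called by that test. They were Nop16, Rrp12, Nop2, Wdr12, Nop56, Gar1, Mybbp1a and the methyltransferase Fbl. The sizes were small: Rrp12 stood 0.56 above zero DOX and 0.30 above high DOX, Nop16 0.36 and 0.32, and Nop2 0.29 and 0.26. Outside the list, Lyar (0.65 and 0.23), the folate transporter Slc19a1 (0.73 and 0.27), Rcc1 (0.52 and 0.28) and Wdr4 (0.31 and 0.41) peaked at low DOX as well, and Anxa5 (-0.30 and -0.64), Gsn (-0.42 and -0.41), Atf5 (-0.36 and -0.33) and Ly6i (-0.35 and -0.53) were lowest there. These genes were picked from the 56 after their values were seen. Genes of a list move together, which Fisher's test does not allow for, and these 56 fell to between 24 and 37 without any of 5 of the day 3 arrays.

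A set of 16 genes stood at least 2-fold apart between KO and wild type in the same direction at each day and dose compared, 11 higher and 5 lower in KO. Xaf1 (3.59 to 5.43), the transcription factors Maf (1.61 to 3.62) and Tbx21 (1.70 to 2.89), Ifitm3 (1.32 to 2.94), Anxa2 (1.08 to 2.60), Alox5ap (1.12 to 3.03), Tmem87a (1.89 to 2.32), Actn1 (1.41 to 2.40), Adgrl2 (1.16 to 3.23), Hddc3 (1.36 to 2.00) and Gm31718 (1.15 to 2.41) were higher. Crisp3 (-4.09 to -5.34), the glutamate decarboxylase Gad1 (-1.33 to -2.21), Gadl1 (-1.09 to -1.83), Kctd14 (-1.19 to -3.42) and Taf15 (-1.09 to -1.74) were lower. All were named after their values were seen. The other probe set of Xaf1 fell at day 0 and was not called at day 3, so the range of Xaf1 holds only for the set used here.

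These 16 genes were chosen for standing apart at both doses of doxycycline as well, so their distance from wild type there follows from the choice. DNA of another strain carried along around Irf4 is argued against for the 15 placed genes, since 0 of these lie on its chromosome and they spread over 9. Gm31718 was not placed. Strain DNA elsewhere cannot be told apart from an effect of genotype: 0 of the 15 placed genes had another of the set within 100 genes, where random sets had a median of 2, but blocks that each hold 1 such gene give no neighbours. With a sex term 15 of the 16 stayed called in all 5 comparisons. Every wild-type array came from a female, so this term is set by KO replicates 1 and 2 against KO replicate 3. It cannot part sex from other traits of that replicate, so sex is not decided by it. No biological explanation was tested.

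For each comparison of 3 against 3 arrays the 10 possible splits are too few for a share under 0.05, and the real count and the highest of the other splits were as follows. KO against wild type gave 3832 and 1293 at day 0, 6048 and 0 at day 1, and 4247 and 0 at day 3; in each, 1 split of 10, the real one, reached the real count. Wild type gave 9932 and 0 at day 1 and 7960 and 1 at day 3 against day 0, and KO against wild type at day 3 gave 5008 and 4 with high and 4164 and 1 with low DOX. Where replicate numbers pair the KO arrays, only the splits that part as many pairs compare with the real one. Those gave 0 in each case, while the highest of all other splits was 0 beside 335 for high against zero DOX at day 1, 0 beside 5923 at day 3, 6 beside 4362 for low against zero DOX at day 3, 1 beside 227 and 4 beside 1557 for high against low DOX at days 1 and 3, and 1 beside 8508 and 36 beside 7600 for KO at days 1 and 3 against day 0. Low against zero DOX at day 1 gave 0 in limma (34 at an unadjusted p under 0.05, fewer than unchanged genes would give in a calibrated test). Each of the other splits gave 0 too, so 10 of 10 were as large.

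For the interaction, 1 of 100 drawn splits of genotype within day, the real one with 3156 genes, was as large. The highest other split, with 3093, exchanged 2 of the day 0 arrays between the genotypes and none at day 3, which ignores the replicate numbers that pair the KO arrays. Of the 28 splits that move KO arrays of a number together at both days, only the real one was as large (highest other 95), a share under 0.05. If wild-type arrays of a number are moved together too, 10 splits remain, too few for such a share (highest other 56). For genes with low DOX apart, 4 of 100 drawn splits of the 9 day 3 arrays gave 56 or more, but these splits ignore the replicate numbers that pair the arrays. Of 100 splits that exchange doses only within a replicate number, drawn from 108, 9 gave 56 or more, the real one among them. Chance is not excluded at 0.05, but this share cannot decide about it, since splits that keep whole dose groups are counted. In the 8 others of these, another whole dose group took the place of low DOX (1466 genes or more, highest 4414), and the rest gave 0. In the first draw the highest, with 4275, likewise set the 3 zero DOX arrays apart. This points to the dose groups as the structure of these samples.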
